A study of Mus musculus with 6 samples.

How the data were processed

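Poly(A) RNA libraries from 3 C2C12 myoblast samples and 3 myotube samples were analysed. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit. The authors deposited raw read counts per gene, identified by Entrez gene ID and symbol, with 1 column for each of the 6 libraries. Per the submitters' processing notes, fastp, STAR and featureCounts were used with the mm10 genome; their versions, their treatment of reads with several matches and the strand setting are not given in the sources used here. Counts of genes that overlap an annotated antisense transcript are therefore uncertain. Among those named, Mb, Cmya5, Cdkn1c and Tagln share the largest parts with one, and others, such as Acss2, Bdh1, Casq1, Me3 and Runx2, smaller parts. Also uncertain are the counts of Igf2, Psph, Spry1 and Aldh1l2, which share windows with another transcript at their own locus.

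The count table held 27179 genes, of which 8724 had 0 counts in all libraries and 1049 had no symbol. The latter were kept under their Entrez ID and took 0.212 to 0.257% of the counts. Of the IDs, 25275 matched the RefSeq gene table of GRCm38, the assembly that mm10 names, and coordinates come from it. Library totals ranged from 10076945 to 11723881 in myoblasts and from 7370169 to 8339589 in myotubes. The 10 most abundant genes took 5.2 to 5.3% of counts in myoblasts and 7.1 to 7.2% in myotubes. All value columns of the table were used.

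The groups come from the sample titles, and each column was matched to its sample by name. Replicates were compared before averaging. No pair was identical, and chi-square per degree of freedom over genes ranged from 1.35 to 3.22 between replicates of a group, so each library was counted as its own sample. Replicate numbers are not described as marking a shared culture, and the main fit had no block.

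Differences were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12800 genes holding at least 99.86% of the counts of each library. Counts were scaled by TMM, with factors of 1.05 to 1.055 in myoblasts and 0.949 to 0.952 in myotubes, and the robust quasi-likelihood F test gave log2 fold changes of myotubes over myoblasts. The standard error (SE) is the absolute log2 change divided by the square root of F. It is too small for large changes where a group has few counts. Dhrs7c, with 1 count in the myoblast group, has an SE of 0.17 beside the wide counting interval given below. A test against a 2-fold change used glmTreat with a log2 threshold of 1. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The biological coefficient of variation was 3.56%. CPM are after TMM scaling. For genes at 0 counts in a group, the fold is a lower bound against 3 counts over the group, which is 0.0881 CPM in myoblasts and 0.134 CPM in myotubes. For 1 to 3 counts, the ratio has an exact binomial interval at 95%. Intervals and bounds cover counting error only.

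The 32 gene lists, their tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 3 tested members, and again with an estimated correlation. The route against the TCA cycle was compared as a difference of mean log2(CPM + 1) by an exact two-sided permutation test. Genes were named by this rule: the 8 highest and 8 lowest log2 changes among called genes with a mean of at least 10 CPM, no overlap between groups and no provisional symbol; the route genes and Cs; and in each list, among called genes with a mean of at least 1 CPM, the 2 largest changes in the direction most members took and the largest in the other direction. Genes outside this rule are marked as named after their values were seen. Some genes are not reported here.

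The gene lists examined after the main results were known, on imprinted genes, the actin cytoskeleton, lysosomes, the proteasome, ribosome biogenesis and hypoxia-inducible genes, are reported in the closing section. The spread between myotube libraries was compared with 10000 random lists matched on expression after the spread of glycolytic and cholesterol genes had been seen.

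Alternatives were DESeq2 1.42.0 size factors, total counts without TMM, the DESeq2 Wald test, limma-voom, no filter, a filter of 1 CPM in at least 3 libraries, replicate number as a block, thinning to the smallest library, removal of mitochondrially encoded genes, and leaving out each library. The lists were also tested without members under 1 CPM, and the route with an offset of 0.25 and as a ratio of summed CPM.

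To find genes with near-identical copies, each 50-base window of the longest GENCODE transcript of list members and named genes was searched, on both strands, in the transcripts of other genes with Python 3.11.15. Where a coding transcript is mentioned, the search used the longest protein-coding transcript and counted copies outside the gene's own locus. The main test was tested on simulated data with the real genes and depths. It recovered 58.7% of genes changed by 0.3 on the log2 scale, 84% at 0.6, 93.6% at 1 and 97.8% at 2, and 12 of its 170 calls were false. Only 46, 50, 47 and 46 changed genes of these sizes were tested among 12800 simulated genes, while 10170 were called in the real data. With so few changed genes the adjusted threshold is stricter, so these shares do not carry over to the real comparison.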

Results

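RNA was sequenced from C2C12 cells, a mouse myoblast line that proliferates in rich serum and fuses into multinucleated myotubes once serum is lowered. The 3 myoblast libraries came from cells kept below confluence in medium with 10% fetal bovine serum. The 3 myotube libraries came from cells held at 100% confluence for 3 days and then kept for 5 days in 2% horse serum with insulin, transferrin and selenium. Both media contained 4 mM glutamine. Serum, the added insulin, transferrin and selenium, cell density and differentiation therefore differ together between the groups. The table of raw read counts held 10597186, 11723881 and 10076945 counts for myoblast libraries 1, 2 and 3, and 7370169, 7795853 and 8339589 counts for myotube libraries 1, 2 and 3. The labels state a harvest in triplicate and name no separate cultures, so p-values measure only the spread between these samples, which may be technical.

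The comparison asks how the transcriptome of these cells differs between the proliferating and the differentiated state. The 8 steepest increases in myotubes were in genes of the contractile apparatus, calcium handling and muscle metabolism, and 6 of them had 0 counts in the myoblast group. Mybpc2, fast skeletal myosin-binding protein C, had 259 ± 18.8 CPM in myotubes (SD, n = 3), at least 2928-fold higher than the level that 3 counts over the myoblast group would give. By the same bound, the muscle form of a cytochrome c oxidase subunit, Cox6a2, was at least 2497-fold higher, the Z-disc protein myotilin (Myot) at least 1599-fold, Cmya5, which overlaps an antisense transcript, at least 758-fold, the slow myosin light chain Myl2 at least 635-fold and the glycogen-targeting phosphatase subunit Ppp1r3a at least 537-fold. Dhrs7c had 1 count in the myoblast group, and its ratio was 5280 with a 95% counting interval of 947 to 209000. Myoglobin (Mb) went from 0.536 ± 0.198 to 2142 ± 313 CPM, a log2 change of 11.95 (SE 0.26, adjusted p = 3.28e-07). Mb had 18 counts in the myoblast group, so this SE is too small. It overlaps an annotated antisense transcript, and the strand setting of the counting is not given in the sources used here, so its level is uncertain.

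The steepest decreases included Id3, an inhibitor of myogenic helix-loop-helix factors, which fell from 260 ± 6.63 to 5.32 ± 0.804 CPM (log2 change −5.60, SE 0.08, adjusted p = 1.37e-27). Id3 had 119 counts in the myotube group, so this SE is also too small. The scaffold protein gene Akap12 fell by 5.62 on the log2 scale, from 188 ± 3.89 to 3.85 ± 1.73 CPM. Car8 fell by 6.71, the collagen gene Col8a2 by 4.94, the PCNA-binding factor gene Pclaf by 4.76, Aldh3a1 by 4.69 and Mxd3 by 4.54. Car8 had only 4 counts in the myotube group, so the size of its change is uncertain. Prl2c3 also had a lower count, with a log2 change of −6.41, but 78.6% of the 50-base windows of its coding transcript have an exact copy in another gene, so its identity within the Prl2c family is uncertain.

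By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 10170 of the 12800 genes tested passed an adjusted p of 0.05, 5146 higher and 5024 lower in myotubes. A change of more than 2-fold was called for 2765 genes, 1587 higher and 1178 lower. The groups did not overlap for 80.5% of the genes tested, where chance gives 10%. Scaling by total counts in place of TMM moved the median of all log2 changes from 0.02 to −0.13, a shift of −0.15, and gave 4269 genes higher and 5935 lower. It turned the sign of 114 called genes, of which 0 passed the threshold under both scalings. The members of the gene lists among them were Ogdh, Atp5a1, Acat1 and Cdon, all named after their values were seen.

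Of the 32 gene lists fixed before the data were examined, 29 had at least 3 tested members, and 16 of these differed from the other genes by camera at an adjusted p of 0.05, 13 higher and 3, serine and nucleotide synthesis, DNA replication and mitosis, lower. With an estimated inter-gene correlation 5 held. These were sarcomere, excitation-contraction coupling, fusion, muscle energy and mitosis. In the other splits of the 6 libraries, camera with the preset correlation still called up to 15 lists. Those splits mix myoblast and myotube libraries unequally in each group, so part of the real difference remains in them. How many of the 16 calls are false therefore cannot be told from them.

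**Figure D1:**
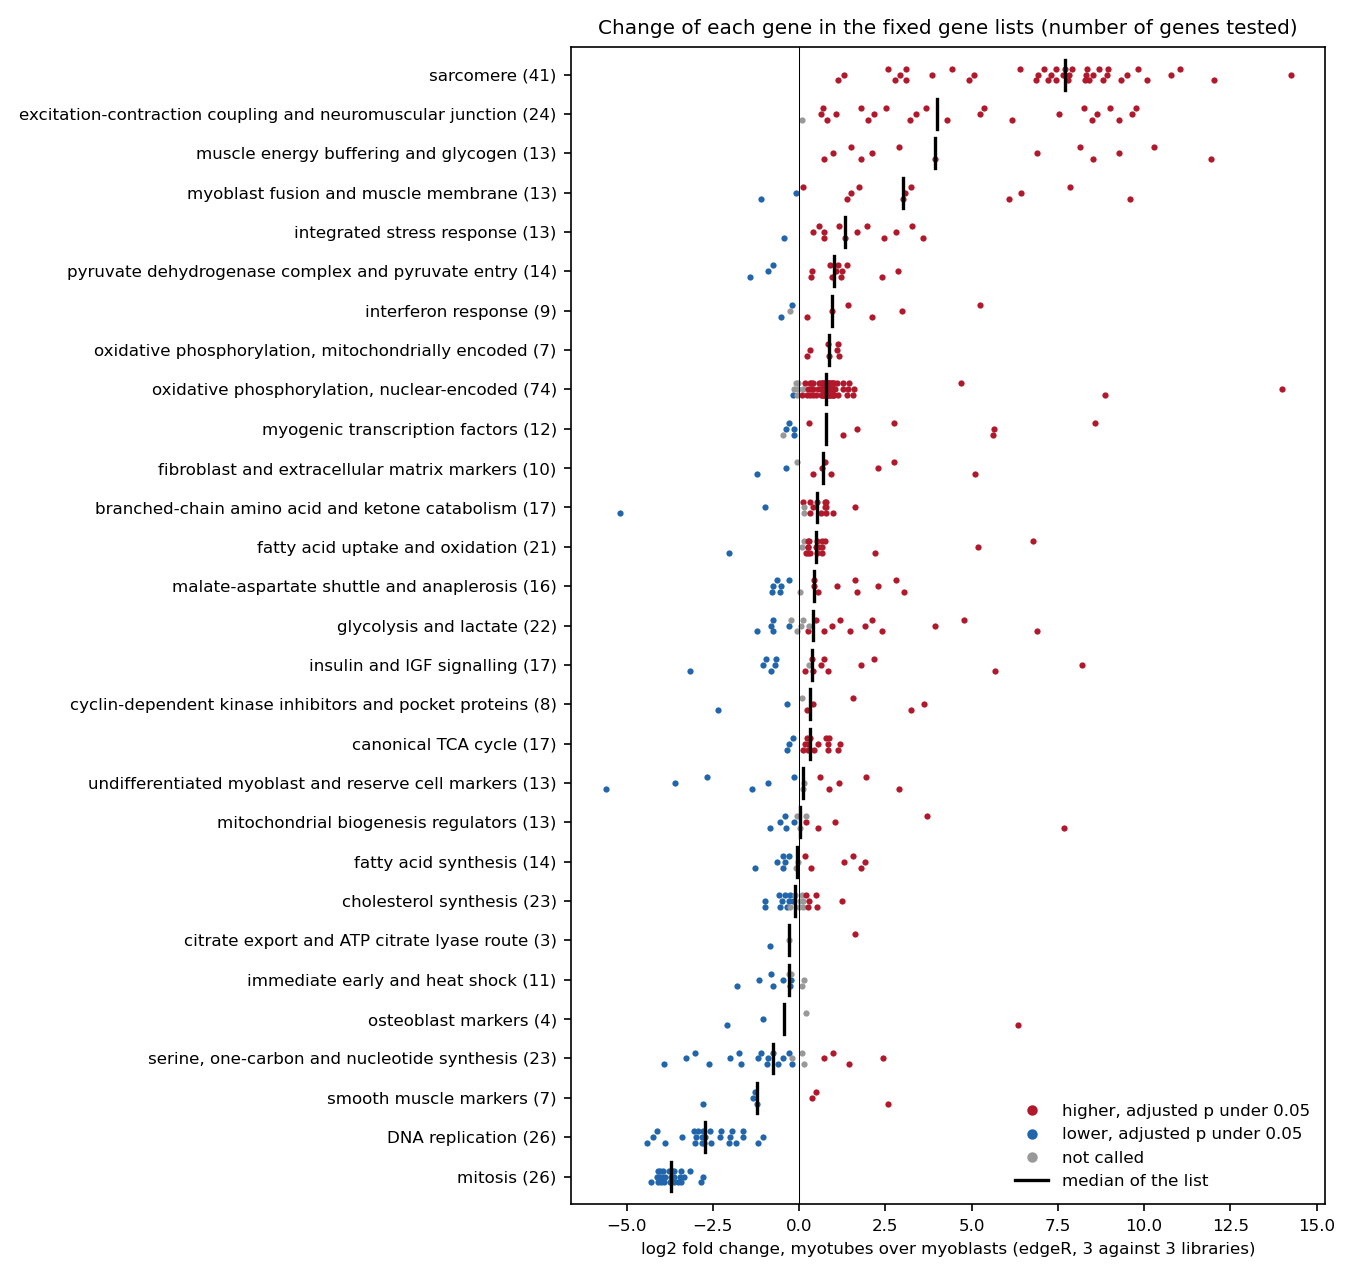
Each point is the log2 fold change of a gene, myotubes over myoblasts, from edgeR on 3 against 3 libraries, arranged by the 29 gene lists with at least 3 tested genes; black bars are list medians and colours show the call. The sarcomere list has the highest median, 7.70, and the mitosis list the lowest, −3.72; fitted changes of genes at 0 counts in myoblasts, such as Mybpc2, depend on the prior count.

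Genes of the contractile apparatus rose together. All 41 tested sarcomere genes rose, with a median log2 change of 7.70 (adjusted p = 2.42e-185 by camera, adjusted p = 0.0135 with an estimated correlation). The median was also 7.70 with the 2 members at 0 counts in myoblasts set to their bounds. Myh4, a fast myosin heavy chain, had a log2 change of 11.05, with copies for 18.9% of its windows, and Actn2 one of 9.84, while the smallest was that of desmin (Des), 1.12; these 3 were named after their values were seen. In the excitation-contraction coupling and neuromuscular junction list 23 of 24 genes rose, with a median of 3.99 (adjusted p = 4.09e-47, adjusted p = 0.0266 with an estimated correlation). The calcium-binding protein calsequestrin (Casq1) went from 0.328 ± 0.124 to 270 ± 15.3 CPM, and Sypl2 was at least 132-fold higher. Rapsn, named after its values were seen, did not pass, with a log2 change of 0.09. All 13 genes of muscle energy buffering and glycogen rose, with a median of 3.93 (adjusted p = 6.91e-25, adjusted p = 0.0266 with an estimated correlation). The mitochondrial creatine kinase Ckmt2 had 1 count in the myoblast group and a ratio of 1820, with a 95% counting interval of 326 to 71800. Adjusted over the list alone, the counts of these 3 lists were the same.

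Among fusion and muscle membrane genes 11 of 13 rose and 2 fell, with a median of 3.02 (adjusted p = 3.71e-17, adjusted p = 0.0315 with an estimated correlation). The muscle caveolin Cav3 rose by 9.59 and the fusion peptide gene Mymx by 7.86 on the log2 scale. They had 4 and 27 counts in the myoblast group, so their SE of 0.18 and 0.11 are too small. Myof, a ferlin of the myoblast membrane, fell by 1.11, and Cdh15, named after its values were seen, by 0.08. Of the 12 myogenic transcription factors 7 rose and 4 fell, with a median of 0.77 (adjusted p = 8.19e-06, adjusted p = 0.0760 with an estimated correlation). Mef2c went from 1.85 ± 0.356 to 706 ± 39.7 CPM and Myf6 from 0.594 ± 0.141 to 30.3 ± 2.65 CPM. Six4 fell by 0.39, Myod1 by 0.16 and Myf5 by 0.13; the last 2 were named after their values were seen. Adjusted over the list alone, the transcription factor list had 7 up and 5 down, and the fusion list the same counts as over all genes. The transcription factor list lost its call in limma-voom (adjusted p = 0.0686, range over 17 alternatives 5.63e-08 to 0.0760).

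Markers of undifferentiated myoblasts and reserve cells moved apart. Of 13 tested, 5 rose and 6 fell, the same adjusted over the list alone, and the list did not differ from other genes (adjusted p = 0.183). Its median was 0.10 while its mean, −0.50, and the camera direction were down; with scaling by total counts the median was −0.04. Id2 fell by 3.60 and Id3 by 5.60, whereas the receptor tyrosine kinase antagonist Spry1 rose by 2.91. Heyl, Cd34, Notch3 and Hey1, named after their values were seen, rose by 1.94, 1.15, 0.86 and 0.59. Pax7, the satellite cell factor, had a log2 change of 0.10 and was not called; it was named after its values were seen.

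Genes of DNA replication and mitosis fell. All 26 DNA replication genes fell, with a median log2 change of −2.74 (adjusted p = 1.09e-22, adjusted p = 0.0511 with an estimated correlation). The replication licensing factor gene Cdc6 fell by 4.40 and the helicase subunit gene Mcm5 by 4.23. All 26 mitosis genes fell, with a median of −3.72 (adjusted p = 6.71e-54, adjusted p = 0.0266 with an estimated correlation), among them the mitotic kinase Plk1, from 117 ± 4.06 to 5.98 ± 0.522 CPM, and the transcription factor Foxm1, from 178 ± 8.34 to 10.3 ± 1.18 CPM. Adjusted over the list alone the counts were again 26 and 26. Of 8 cyclin-dependent kinase inhibitors and pocket proteins 5 rose and 2 fell, also when adjusted over the list alone (median 0.32, adjusted p = 0.0217, adjusted p = 0.170 with an estimated correlation). Cdkn1a went from 209 ± 3.36 to 1982 ± 25.3 CPM and Cdkn1c, which overlaps an annotated antisense transcript and is uncertain for that reason, rose by 3.61, while Rbl1 fell by 2.36. Rb1 rose by 1.55, Cdkn1b by 0.42 and Cdkn2d by 0.22, and Cdkn2c fell by 0.35; these 4 were named after their values were seen. This list also lost its call in limma-voom (adjusted p = 0.142) and with no filter on low counts (adjusted p = 0.0742), the range over 17 alternatives being 5.33e-05 to 0.170.

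The series title concerns a non-canonical tricarboxylic acid (TCA) cycle. In that route citrate leaves mitochondria through the carrier Slc25a1, is cleaved in the cytosol by ATP citrate lyase (Acly), and its carbon returns as malate made by cytosolic malate dehydrogenase (Mdh1). The 3 genes did not move together. Mdh1 rose 3.05-fold, from 153 ± 3.14 to 469 ± 31.2 CPM (SD, n = 3; log2 change 1.61, SE 0.05, adjusted p = 6.57e-21). Acly fell to 56.3% of its myoblast level, from 413 ± 7.31 to 233 ± 15.2 CPM (log2 change −0.83, SE 0.04, adjusted p = 3.61e-15). Slc25a1 had 64.5 ± 3.39 CPM in myoblasts and 53.6 ± 10.5 CPM in myotubes, and did not pass (log2 change −0.28, SE 0.12, adjusted p = 0.0601). Citrate synthase (Cs), the mitochondrial entry step, fell to 87.9% of its myoblast level, from 615 ± 3.77 to 541 ± 1.55 CPM (log2 change −0.19, SE 0.04, adjusted p = 4.38e-05). In the mouse assembly GRCm38, Slc25a1 (Entrez gene 13358) lies on chromosome 16 at 17925211 to 17928219, Acly (104112) on chromosome 11 at 100476352 to 100528000, Mdh1 (17449) on chromosome 11 at 21556692 to 21571934 and Cs (12974) on chromosome 10 at 128337727 to 128362482; counts cover their annotated exons.

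Of the 17 canonical TCA cycle genes 14 rose and 3 fell, also when adjusted over the list alone. The subunits Sucla2 and Dld rose most, by 1.18 and 1.14 on the log2 scale (SE 0.05 and 0.04). Cs fell by 0.19, Mdh2, named after its values were seen, by 0.28 and Suclg2 by 0.34. The median change was 0.31, and the list did not pass against other genes (adjusted p = 0.0534 by camera, adjusted p = 0.258 with an estimated correlation). With scaling by total counts 11 rose and 3 fell, with a median of 0.17. The list passed in 5 of 17 alternatives, the adjusted p ranging from 0.00390 to 0.258, and without myotube library 1 it was 0.0216. Suclg2 shares 21.8% of its windows with a pseudogene and lost its call in 4 of 15 alternatives, among them those without myoblast library 2 (adjusted p = 0.0773) and without myotube library 2 (adjusted p = 0.115, range 0.0013 to 0.115). The route list had 1 gene up and 1 down over all genes and, adjusted over the list alone, 1 up and 2 down. Its median was −0.28, its mean 0.17 and its camera direction up (adjusted p = 0.713). Slc25a1 was called in 7 of 15 alternatives, including those without myotube library 1 (adjusted p = 0.00346) or 2 (adjusted p = 0.0301), with a range of 2.26e-06 to 0.174, and without myotube library 3 its log2 change was −0.12.

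**Figure D2:**
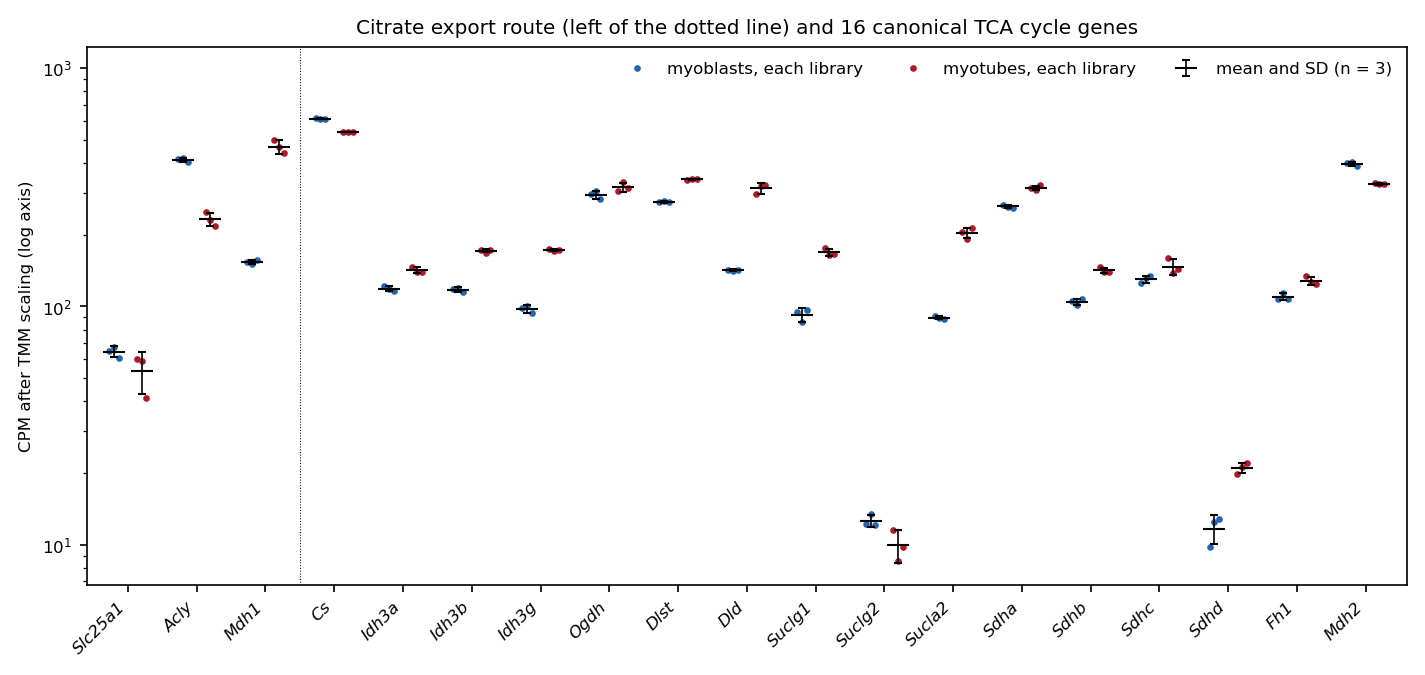
CPM after TMM scaling, on a log axis, for the 3 citrate export route genes and 16 of the 17 canonical TCA cycle genes; coloured points are single libraries and black marks the mean and SD of 3. Mdh1 is higher in all 3 myotube libraries and Acly lower, while Slc25a1 ranges more widely relative to its mean among myotubes, with an SD of 10.5 CPM around 53.6 CPM.

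Within each library, the mean log2(CPM + 1) of the route genes minus that of the TCA cycle genes was 0.31 ± 0.02 in myoblasts and 0.05 ± 0.16 in myotubes (SD, n = 3), a difference of −0.25. An exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 libraries allow, so this comparison cannot pass 0.05. The values were 0.32, 0.31 and 0.29 in myoblast libraries and 0.16, 0.13 and −0.12 in myotube libraries 1, 2 and 3. The difference was −0.16 without myotube library 3 and −0.08 as a ratio of summed CPM. Ratios of single enzymes, chosen after the values were seen, had opposite signs. The log2 difference between groups was −0.64 for Acly over Cs and 1.89 for cytosolic Mdh1 over mitochondrial Mdh2. Each comparison in this family of 4 had an exact permutation p = 0.1 and an adjusted value of 0.1.

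Genes of pyruvate entry and its control were mostly higher, a count that pools enzymes with regulators that inhibit them. Of 14 genes of the pyruvate dehydrogenase complex and its regulators 11 rose and 3 fell, the same adjusted over the list alone, with a median of 1.01 (adjusted p = 0.0137, adjusted p = 0.220 with an estimated correlation). Regulators of opposite action rose: the inhibitory kinase Pdk2 by 2.87 and the activating phosphatase Pdp1 by 2.41 on the log2 scale (SE 0.07 and 0.06). The starvation-induced kinase Pdk4 fell by 1.42, and Pdk3 fell by 0.91 and Pdp2 by 0.77, both named after their values were seen. In the malate-aspartate shuttle and anaplerosis list 9 of 16 rose and 6 fell, also when adjusted over the list alone, and the list did not pass (median 0.42, adjusted p = 0.130) except in the DESeq2 Wald test (adjusted p = 0.0338, range over 17 alternatives 0.0338 to 0.261). Mitochondrial malic enzyme 3 (Me3) rose by 3.05, alanine aminotransferase 2 (Gpt2) went from 73.5 ± 5.42 to 512 ± 47.2 CPM, and malic enzyme 2 (Me2) fell by 0.79.

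Lipid synthesis genes, which draw on the acetyl-CoA that Acly makes, were called in both directions. Fatty acid synthesis had 6 genes up and 6 down of 14, the same adjusted over the list alone (median −0.05, mean 0.25, camera direction up, adjusted p = 0.323). Acss2, which makes acetyl-CoA from acetate, rose by 1.91 and the acyl-CoA synthetase Acsl3 by 1.81, while the elongase Elovl6 fell by 1.29. Cholesterol synthesis had 6 up and 10 down of 23, or 6 and 9 adjusted over the list alone (median −0.11, adjusted p = 0.574). With scaling by total counts, cholesterol synthesis had 3 up and 12 down (median −0.25) and fatty acid synthesis 5 up and 8 down (median −0.20). Sqle fell from 283 ± 1.75 to 143 ± 19.2 CPM, while Dhcr7 rose by 1.24. The cholesterol list also varied between the myotube libraries, with a median SD of log2(CPM + 1) of 0.140 against a 95th percentile of 0.0831 in expression-matched random lists. This comparison was chosen after that spread was seen, and so describes it and is no separate test.

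Most respiratory chain genes rose. Of 74 nuclear-encoded subunit genes 67 rose and 1 fell, also when adjusted over the list alone, with a median log2 change of 0.78 (adjusted p = 8.14e-09, adjusted p = 0.0722 with an estimated correlation). With Cox6a2 set to its bound the median was also 0.78. The largest increases were those of muscle isoforms: beside Cox6a2, Cox8b had 3 counts in the myoblast group and a ratio of 540, with a 95% counting interval of 184 to 2620, while the ubiquitous isoform Cox6a1 fell by 0.16. All 7 tested mitochondrially encoded mRNAs rose, also when adjusted over the list alone (median 0.88, adjusted p = 0.00194, adjusted p = 0.252 with an estimated correlation). ND6 rose by 1.15 and COX1 by 1.12, and mitochondrial genes took 2.1 to 2.2% of counts in myoblasts and 3.7 to 3.8% in myotubes. COX1 has exact copies elsewhere for 51.1% of its windows, so its level is uncertain. Counts of mitochondrial mRNAs, ND6 among them, also depend on the strand setting of the counting, which is not given in the sources used here. The other 6 mRNAs, COX2, COX3, ATP6, ATP8, ND3 and ND4L, had at most 4 counts in either group and were not tested.

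**Figure D3:**
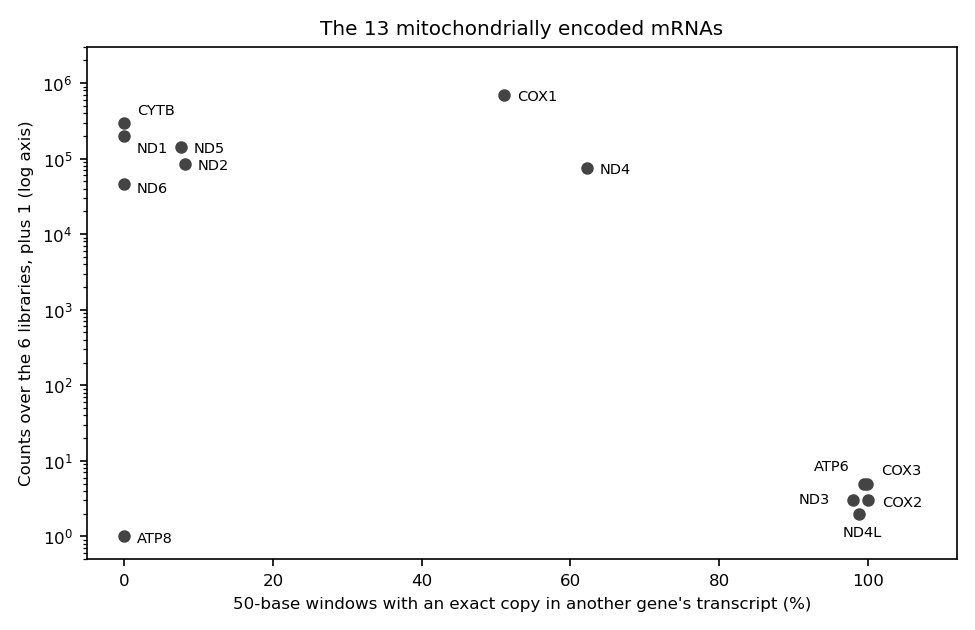
Total counts over the 6 libraries plus 1, on a log axis, against the percentage of 50-base windows with an exact copy in another gene's transcript, for the 13 mitochondrially encoded mRNAs, 1 point each. COX2, COX3, ATP6, ND3 and ND4L, 98 to 100% copied, lie near 0 counts, as does ATP8 with no window copied in an annotated transcript.

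Regulators of mitochondrial biogenesis did not move as a list (5 up and 5 down of 13, also when adjusted over the list alone; median 0.03, mean 0.85, camera direction down, adjusted p = 0.888), and the median was −0.11 with scaling by total counts and −0.02 without myotube library 3. The nuclear receptor Esrrg was at least 31.0-fold higher and the coactivator Ppargc1a rose by 3.70, whereas Nrf1 fell by 0.83. Named after their values were seen, Tfb2m, Tfb1m and Esrra rose by 1.03, 0.55 and 0.21, and Polg, Ppard, Polrmt and Gabpa fell by 0.56, 0.42, 0.39 and 0.15; Tfb2m has copies for 39.6% of its windows. Among genes of fatty acid uptake and oxidation 18 of 21 rose and 1 fell, the same adjusted over the list alone (median 0.48, adjusted p = 0.0342, adjusted p = 0.258 with an estimated correlation). The fatty acid transporter Cd36 went from 0.605 ± 0.455 to 65.7 ± 3.56 CPM, and Fabp3, with copies for 29.2% of its coding windows, rose by 5.18. Cpt1a, the liver-type carnitine palmitoyltransferase, fell by 2.04. This list lost its call with scaling by total counts (adjusted p = 0.0504, range over 17 alternatives 0.00148 to 0.258). Branched-chain amino acid and ketone catabolism had 13 up and 2 down of 17, also when adjusted over the list alone, and did not pass (median 0.52, adjusted p = 0.251) except in limma-voom (adjusted p = 0.0284) and with no filter (adjusted p = 0.0245), the range over 17 alternatives being 0.0245 to 0.609. Aldh6a1 rose by 1.62 and Dbt by 0.99, while the ketone body enzyme Bdh1 fell to 1 count in the myotube group, a myoblast over myotube ratio of 47.2 with a 95% counting interval of 8.2 to 1890. The other gene that fell, Oxct1, was lower by a log2 change of −0.98 and was named after its values were seen.

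Among glycolytic genes more rose than fell. Of 22 tested 12 rose and 5 fell, also when adjusted over the list alone (median 0.40, adjusted p = 0.00139, adjusted p = 0.403 with an estimated correlation). Muscle phosphoglycerate mutase Pgam2 went from 1.75 ± 0.470 to 210 ± 4.62 CPM and the insulin-responsive glucose transporter Slc2a4 rose by 4.79, while the ubiquitous transporter Slc2a1 fell by 1.23. Pgam1, Pfkl, Hk1 and Slc16a1, named after their values were seen, fell by 0.81, 0.76, 0.75 and 0.28, and Pgam1 is uncertain because 41.5% of its windows have copies elsewhere. They also varied between the myotube libraries, with a median SD of log2(CPM + 1) of 0.162 against a 95th percentile of 0.0821 in random lists matched in the same way, again a description of a spread already seen. The glycolysis list lost its call in limma-voom (adjusted p = 0.0686, range over 17 alternatives 1.3e-05 to 0.403). Gapdh, named after its values were seen, had 14.4 ± 1.30 CPM in myotubes, and 82.5% of its coding windows have copies elsewhere, so its level is uncertain.

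The joint list of serine, one-carbon and nucleotide synthesis mostly fell, but its members that rose all belong to the serine and one-carbon part. Of 23 serine, one-carbon and nucleotide synthesis genes 16 fell and 4 rose, the same adjusted over the list alone (median −0.77, adjusted p = 0.00033, adjusted p = 0.170 with an estimated correlation). Thymidine kinase 1 (Tk1) fell by 3.91 and thymidylate synthase (Tyms) by 3.28. Of the 4 that rose, Aldh1l2 rose by 2.43, and Mthfd2, Psph and Psat1, named after their values were seen, by 1.45, 0.97 and 0.71. Phgdh and Shmt2, with log2 changes of 0.09 and 0.13, were not called and Mthfd1l fell by 0.61; these 3 were also named after their values were seen. Integrated stress response genes rose in 12 of 13 cases, also when adjusted over the list alone (median 1.33, adjusted p = 2.08e-05, adjusted p = 0.252 with an estimated correlation). Vldlr rose by 3.60 and Trib3 by 3.27, and the cystine transporter Slc7a11 fell by 0.44. Of 11 immediate early and heat shock genes 7 fell and 4 were not called, or 6 and 5 adjusted over the list alone (median −0.30, adjusted p = 0.176). This list passed in limma-voom (adjusted p = 0.0499) and with no filter (adjusted p = 0.0256), the range over 17 alternatives being 0.0256 to 0.509. Egr1 fell by 1.17, and Hspa1b was lower by a log2 change of −1.80 but shares 62.3% of its windows with other genes and is uncertain.

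Insulin and IGF signalling genes had 10 up and 6 down of 17, also when adjusted over the list alone, and did not pass (median 0.37, adjusted p = 0.154). Insulin was added to the myotube medium, so its effect cannot be told apart from that of differentiation. The growth factor Igf2, which shares windows with another transcript at its locus, went from 8.68 ± 1.42 to 438 ± 20.6 CPM and the ubiquitin ligase Trim63 rose by 8.21, while Igfbp2 fell from 1078 ± 14.7 to 120 ± 6.82 CPM. Interferon response genes had 6 up and 2 down of 9, the same adjusted over the list alone (median 0.97, adjusted p = 0.612). Ifit1 rose by 2.98 and Isg15 by 2.10, at mean levels of 2.63 and 3.46 CPM in myotubes. Oasl2 fell by 0.51 (adjusted p = 0.0341), and lost its call in 6 of 15 alternatives, among them those without myoblast library 1 (adjusted p = 0.105) or 2 (adjusted p = 0.0898) and without myotube library 1 (adjusted p = 0.0610) or 3 (adjusted p = 0.114), with a range of 0.00758 to 0.164.

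Markers of other cell types had no common direction. Fibroblast and matrix genes had 7 up and 2 down of 10, also when adjusted over the list alone (median 0.70, adjusted p = 0.000268, adjusted p = 0.252 with an estimated correlation). The matrix genes Dcn and Postn rose by 5.10 and 2.76, and the fibroblast receptor Pdgfra fell by 1.21, as did Fn1, named after its values were seen, by 0.38. Smooth muscle markers had 3 up and 4 down of 7, the same adjusted over the list alone (median −1.21, adjusted p = 0.251), where Cnn1 fell by 2.79 and Myl9 by 1.33, and Lmod1 rose by 2.57 on the log2 scale. Tagln, which overlaps an antisense transcript, and Cald1 fell by 1.28 and 1.21 and Smtn and Acta2 rose by 0.48 and 0.38, all named after their values were seen. Of 4 tested osteoblast markers 1 rose and 2 fell, also when adjusted over the list alone (median −0.42, mean 0.85, camera direction down, adjusted p = 0.0758). In the DESeq2 Wald test this list passed, with a median of 0.01 (adjusted p = 0.00716, range over 17 alternatives 0.00716 to 0.436). Spp1 fell from 3815 ± 105 to 898 ± 15.5 CPM and Runx2 by 1.03, and Bglap2, with copies for 88.2% of its windows, had a ratio of 117 with a 95% counting interval of 20.5 to 4700. Of 9 adipocyte markers 2 were tested, the regulators Cebpa and Pparg, which fell by 1.01 and 0.47, also when adjusted over the list alone. Of the 9 macrophage and leukocyte markers 1 was tested, Cd68, with a log2 change of −0.14 that was not called; it was named after its values were seen. Of 7 endothelial markers 1 was tested, Vwf, which rose, also when adjusted over the list alone, to 3.88 ± 0.855 CPM, a ratio of 65.6 with a 95% counting interval of 17.6 to 550.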

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

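All alternatives below were planned before the data were examined. The count of genes past the threshold ranged from 9745 with the DESeq2 Wald test to 11105 with no filter, and the genes called there and in the main analysis had 0 changes of direction. The 2-fold count ranged from 2271 with the DESeq2 Wald test to 3204 with no filter. Of the 95 named genes 92 were called with the same sign throughout. The list count was 5 with an estimated correlation and 15 to 19 otherwise. The TCA cycle list passed in the DESeq2 Wald test (median 0.307), limma-voom (0.314), with no filter (0.267), after thinning (0.297) and without myotube library 1 (0.317), and its median ranged from 0.307 to 0.318 when each library was left out; the cause was not tested. The route difference was −0.082 as a ratio of summed CPM, where it moved by more than 1 SD of the wider group, a bound set after the values were seen.

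Some list medians turned sign; the cause was not tested. The biogenesis median was −0.112 with total counts, −0.012 with no filter and −0.016 to 0.087 when each library was left out. The reserve cell median was −0.042 with total counts, where the median of all genes also shifted. The osteoblast median, −0.422 in the main analysis, was 0.007 with the DESeq2 Wald test, where the list passed. The macrophage median was 0.051 with that test and 0.222 with no filter, where more members were tested. Thinned to the smallest library, 9819 genes were called. In data simulated at these depths, but with far fewer changed genes, 58.7% of the changes of 0.3 on the log2 scale were recovered. That share does not carry over to the real data, and how much of the rest is due to depth was not tested.

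With the replicate number as a block (replicate block), 10161 genes, 2765 past 2-fold and 16 lists were called, and the route difference was −0.252. Slc25a1 passed there (log2 change −0.276, adjusted p = 0.000871). Deviations of same-numbered samples correlated at 0.0077, 0.0426 and 0.0267, each sample correlating best with its own number, which is a hint from the data and not a pairing by design. The block changed no other call of a named gene or list.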

Other observations

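The lists in this part were chosen after the main results were seen, with their tests fixed before their own values were examined. The Gapdh test on the coding transcript was chosen only after the result on the longest transcript was seen, and so was the rule that a gap to a random bound must exceed the bootstrap error. The spread of the glycolysis list was compared with random lists after it was seen. Genes of the actin cytoskeleton and focal adhesions, which anchor spread cells to their substrate, were mostly lower in myotubes. Of 26 tested 21 fell and 5 rose, the same adjusted over the list alone, with a median log2 change of −0.80 (adjusted p = 1.21e-07 by camera over 5 lists, unadjusted value 2.42e-08, adjusted p = 0.286 with an estimated correlation). The non-muscle alpha-actinins Actn1 and Actn4 fell by 1.53 and 1.14, and the 5 that rose were Flnc, Itgb1, Pxn, Arpc3 and Itga5, all named after their values were seen. Actb, Vim and Flna, with log2 changes of −1.62, −1.30 and −1.75, had been seen before and were left out of that list. Of 20 ribosome biogenesis genes 14 fell and 2 rose, with a median of −0.45 (adjusted p = 0.0316 by camera, unadjusted value 0.0126, adjusted p = 0.727 with an estimated correlation). Those that rose were Rrn3 and Nop14, named after their values were seen. Near-identical copies were not searched for these added lists.

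Imprinted genes other than H19, Igf2, Igf2r and Cdkn1c, which had been seen before and were left out, did not pass as a list. H19, named after its values were seen, rose from 1796 to 15871 CPM (log2 change 3.14) and took 1.38 to 1.57% of the counts in myotubes, but the other imprinted genes moved both ways. Of 17 tested, 10 rose and 4, Peg10, Ndn, Impact and Peg3, named after their values were seen, fell (median 0.30, mean 0.74, camera direction down, adjusted p = 0.975 by camera, unadjusted value 0.975). Lysosome and autophagy genes had 14 up and 9 down of 25 (median 0.34, adjusted p = 0.340 by camera, unadjusted value 0.204), and proteasome genes 14 up and 7 down of 26 (median 0.13, adjusted p = 0.929, unadjusted value 0.743).

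After thinning all libraries to the smallest total, 9819 genes were called, 0.965 of the 10170 called with all reads, so the lower depth of the myotube libraries does not account for the count. For each of the 3 counts, of genes, of genes past 2-fold and of gene lists, 1 of the 10 splits of the 6 libraries, the real one, gave a value as large, and 10 splits are too few for a share under 0.05. The real values were 10170, 2765 and 16, and the highest of the other splits were 0 genes and 0 genes past 2-fold by edgeR's quasi-likelihood test, with at most 19 genes at an unadjusted p under 0.05, and 15 lists by camera. Every other split mixes myoblast and myotube libraries within each group. The mixing widens the spread within groups, so few gene calls were bound to follow, while part of the real difference stays in the list tests. These splits therefore do not show how many calls chance would give. Medium, density and differentiation differ together, so which of these the differences follow was not tested.

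Of the 13 mitochondrially encoded mRNAs 6 had at most 4 counts in a group, and a candidate explanation is that reads matching nuclear copies were not counted: the median share of 50-base windows with an exact copy in another gene was 0.992 for these 6 and 0.076 for the 7 that were counted. For 5 of the near-0 genes the main copies lie on chromosome 1, such as Gm28661 for COX2 at 24614885 to 24615565. ATP8 had 0 counts with no window copied in an annotated transcript, and genome sequence outside transcripts was not searched, so its case stays open, while ND4 and COX1 were counted with 62.2% and 51.1% of their windows copied. Gapdh, at 10.2 CPM in myoblasts, had a share of 0.278 on its longest transcript, between the bounds set for the test, and of 0.825 on its longest coding transcript, which may point to reads shared with its pseudogenes. No biological explanation was tested for these genes.

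Glycolytic genes differed between myotube libraries, with a median SD of 0.162 on the log2 scale and list means of 7.66, 7.48 and 7.34 in libraries 1, 2 and 3. A hypothesis is that oxygen-regulated genes differed between these samples: 20 hypoxia-inducible genes outside the glycolysis and pyruvate lists had a median SD of 0.2346, above the 95th percentile of matched random lists, 0.0852, with list means of 6.83, 6.56 and 6.39. Against myoblasts 15 of these genes rose and 1, Pfkfb4, fell, with a median log2 change of 1.25, and Car9, like Pfkfb4 named after its values were seen, had 169 ± 53.5 CPM in myotubes and 2.32 ± 0.332 CPM in myoblasts. The cholesterol list spread in the same order, with means of 6.66, 6.51 and 6.40 and a median SD of 0.140 against a 95th percentile of 0.0831. The spread is thus not particular to oxygen-regulated genes. Random lists hold genes that need not vary together, so they are a low bar for a co-regulated list. If the libraries stood at different stages of differentiation, sarcomere genes would be expected to spread too; their median SD was 0.0599, at the 88th percentile of matched lists and under the 95th, 0.0654, but by less than its bootstrap error of 0.0072, so this test leaves differing stages open, although the sarcomere list means of 9.41, 9.44 and 9.42 were close together and argue against a shift of that list as a whole. Whether oxygen, cell density or handling differed between the samples was not tested.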
